A study of Mus musculus with 6 samples.

How the data were processed

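Total RNA from sorted bone marrow megakaryocyte progenitors was amplified, labelled with biotin and hybridised to Illumina mouse bead arrays, per the labels. There were 6 arrays, 3 from Scl wild-type mice and 3 from mice with floxed Scl, all with Pf4-Cre, and groups and replicate numbers were taken from the sample titles. The deposited table that was not normalized holds log2 values, as the values show: they are log2 signals with no between-array scaling. A detection score for each probe and array was deposited beside the signal, under a header that names a detection p-value, but the deposited score runs the other way, with 1 for bright probes (lowest rank correlation with the signal 0.997), so 1 minus the score was used as the detection p. The authors' second deposited table holds log2 values with the same distribution on every array, and its lowest rank correlation with the same array's signal was 1.00, against at most 0.933 between different arrays. It lay within 0.0865 of plain quantile normalization of the first table. The submitters' processing notes name limma with no version; the scanner software and other steps are not given in the sources used here. The median deposited signal was 6.65 and 6.62 (log2) on wild-type arrays 1 and 2 and between 6.43 and 6.46 on the other 4 arrays, and every column of the normalized table had a median of 6.46.

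Signals were returned to a linear scale and processed with neqc of limma 3.58.1 in R 4.3.3, which corrects background by a normal-exponential model, infers the negative controls from the detection p, adds an offset of 16 and quantile normalizes. Probes with a detection p under 0.05 on at least 3 arrays were kept. Background correction widens the fold changes of dim probes, and quantile normalization would hide a shift of most genes in one direction. The platform annotation gave 1 gene symbol for 29976 of the 46632 probes, several for 10 and none for 16646, which are unnamed here; symbols were looked up by gene identifier in the RefSeq table of assembly GRCm38.p6, which changed 0 of them and lacked 55 of the probes with 1 symbol. That table was used only for names, chromosomes and the order of genes. Of the 16122 kept probes, 3907 had no gene. The brightest kept probe, by its mean over the 6 arrays, stood for each of 8946 genes. Of the called genes with several kept probes, 21 had all probes changing in one direction and 1, Hyi, did not. At the level of single probes, 73 passed, of which 19 had no gene name. Gp1ba and Tubb1, which had been fixed for naming, were not analysed here, and 1 other fixed gene is not reported here.

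Groups were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05, and every adjusted p of a gene comes from this model. Where a gene was not above background on any array of a group, the fold is a bound: the mean of the brighter group over the mean, for the other group, of the higher of the lowest signal detected on each array and the probe's own. There were 31 gene lists, of which 30 had at least 3 tested genes, and these were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. With an estimated correlation 0 lists passed and 1, ribosome biogenesis and Myc targets, had an unadjusted p under 0.05. With fry, which asks whether the genes of a list move on balance one way, 0 passed and 6 had an unadjusted p under 0.05, while its mixed test, for changes in either direction, called 11. Neither compares a list with other genes. The list of sex-linked genes, Xist and Y chromosome genes, had 3 tested members and a camera adjusted p of 0.741. A difference in sex would move Xist and Y chromosome genes in opposite directions, which can cancel in this test of a shift one way. The log2 fold changes were -3.00 for Xist, 0.87 for Eif2s3y and -0.18 for Uty, so the p does not show whether the groups differ in sex.

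The groups, tests, gene lists and most alternatives were chosen before the data were examined. The genes named were the target and 20 other fixed genes, the 12 called genes with the largest and the 12 with the smallest fold changes among those whose groups did not overlap, and, from each list, a selection of the 4 genes with the smallest p, or 6 for a list past the threshold. Alternatives were the authors' normalized values, no background correction, median scaling, no filter and a stricter one (detection p under 0.01 on all 6 arrays), an eBayes prior with trend and robust estimation, array weights, the replicate number as a block, the mean of a gene's probes, other thresholds, other list tests, and leaving out each array. No batch, chip or scan date was given in the sources used here.

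The tests were checked on simulated data with the real genes' means and spreads over 8946 genes, for the comparison of Scl-deleted with wild-type arrays. At log2 changes of 1, 2 and 3, 65.7%, 97.0% and 98.5% of the changed genes were recovered, with 6 false calls among 180. With no change simulated 0 genes were called, and a list shifted by 0.5 was the 1 list called. Genes and arrays were simulated as independent of one another. The check therefore does not cover arrays that resemble each other or lists of correlated genes, such as the histone list with an estimated correlation of 0.483.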

Results

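Gene expression was measured in megakaryocyte progenitors, the bone marrow cells that give rise to platelets, sorted from mice of 3 to 4 months of the strain mix 129SVxC57Bl/6. All animals carried Cre recombinase under the Pf4 promoter, which is active in the megakaryocyte lineage. The control group was wild-type at the Scl locus and the other group carried floxed Scl alleles that the design describes as fully excised. Scl, whose gene symbol is Tal1, encodes a basic helix-loop-helix transcription factor required for blood cell formation. There were 3 arrays of each genotype, 1 for each RNA sample, and each array held 46632 probes. Between 15183 and 16338 probes per array lay above background, and 16122 probes were kept, which gave 8946 genes with 1 probe each. The labels do not say whether the 3 samples of a group came from separate animals or pools, so the p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision of every value below.

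The comparison asked which genes differ in megakaryocyte progenitors when Scl is removed. Tal1 itself was lower in the Scl-deleted cells, at a log2 intensity of 10.83 ± 0.90 (SD, n = 3) against 13.13 ± 0.26 (SD, n = 3) in wild-type cells. Its log2 fold change was -2.30 ± 0.39 (SE), 4.93-fold, with a limma adjusted p of 0.0352, and all 3 Scl-deleted arrays lay below all 3 wild-type arrays. Tal1 signal stayed far above background on the 3 Scl-deleted arrays, at 11.22, 9.80 and 11.47, where the lowest detected signal was 5.27 to 5.40. Whether its only probe lies in the deleted part of the gene is not given in the sources used here, so the probe may not check the deletion. In all, 110 genes passed an adjusted p of 0.05, of which 81 were higher and 29 lower in Scl-deleted cells, and 1431 genes had an unadjusted p under 0.05. Over all tested genes the groups did not overlap in 19.6%, against an average of 10% over all splits into 3 arrays against 3. Genes vary together, so a single split can exceed that average whatever its cause, and the share alone does not show an effect of genotype. Without the detection filter, with more genes tested, 27 of the 110 genes passed, among them Myo18b, Chst1, Megf10, Col18a1, Serpina3b, Selp, Fcgr2b, Homer2 and Hspa5. Without wild-type arrays 1, 2 and 3 in turn, 19, 16 and 695 genes passed, and without Scl-deleted arrays 1 and 2, 44 and 34 passed; 14 of the 110 genes passed in each of the 6 fits that left out 1 array. The adjusted p of Tal1 was 0.103 without wild-type array 1, 0.156 without wild-type array 2 and 0.0767 without Scl-deleted array 1, with log2 fold changes of -2.45, -2.23 and -2.50. It was 0.133 without the detection filter and 0.0675 with a trend and robust prior, with a range of 0.0109 to 0.385 over all alternatives.

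**Figure D1:**
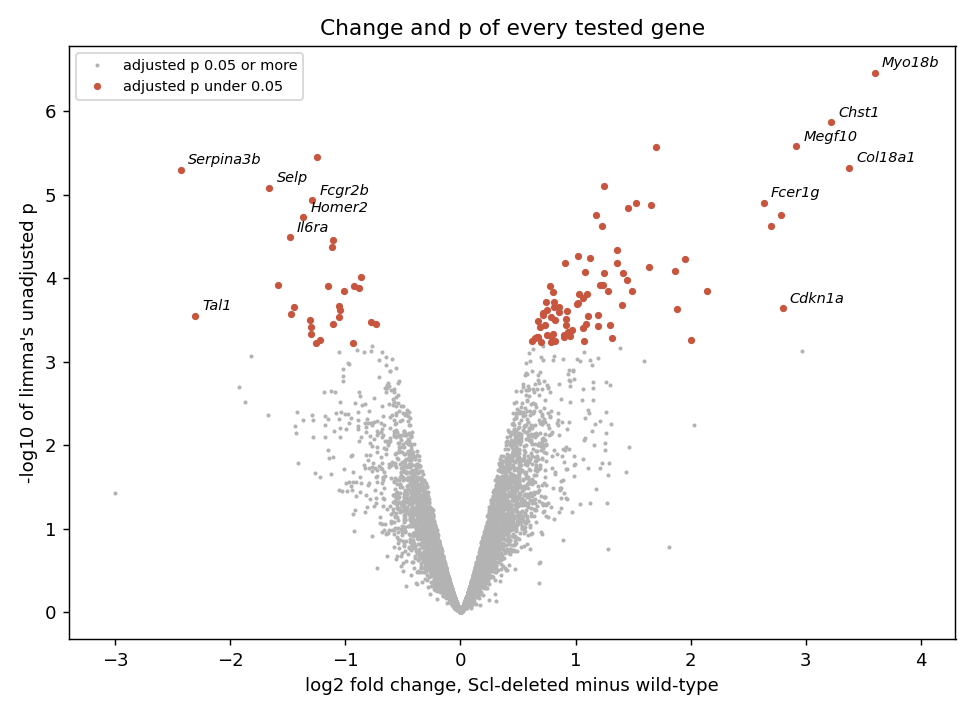
Each point is 1 of the 8946 tested genes, with the log2 fold change of Scl-deleted over wild-type cells on the x axis and the negative log10 of limma's unadjusted p on the y axis. The 110 genes with an adjusted p under 0.05 are red, and 81 of them lie to the right of 0; the wild-type level of Myo18b was not above background.

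The genes with the largest rises encode proteins of several kinds. Myo18b, an unconventional myosin, was not well above background on any wild-type array and was at least 7.52-fold higher in Scl-deleted cells (adjusted p = 0.00311). Col18a1, which encodes the collagen XVIII alpha chain, rose 10.4-fold from 7.59 ± 0.60 to 10.97 ± 0.51 (log2 intensity, SD, n = 3 each; limma adjusted p = 0.00637). Chst1, a carbohydrate sulfotransferase gene, rose 9.33-fold and Megf10, which encodes an engulfment receptor, rose 7.55-fold. Rab44, a member of the Rab small GTPase family, rose 6.89-fold. Alox5, which encodes the 5-lipoxygenase that starts leukotriene synthesis, rose 6.50-fold from 8.38 ± 0.61 to 11.08 ± 0.46. Fcer1g, the signalling chain shared by several Fc receptors and the platelet collagen receptor, rose 6.21-fold from 9.91 ± 0.44 to 12.54 ± 0.52 (adjusted p = 0.00910). Emilin2, an extracellular matrix gene, Arpp21 and P2ry14, which encodes a receptor for UDP-sugars, rose 4.42-fold, 3.86-fold and 3.68-fold. Abat, the GABA transaminase gene, was not well above background on the wild-type arrays and was at least 2.47-fold higher. Of the genes of this paragraph, Myo18b, Col18a1, Chst1, Megf10, Rab44 and Fcer1g kept an adjusted p under 0.05 whichever array was left out. Without background correction the log2 fold changes were smaller, at 2.07 for Myo18b, 2.15 for Chst1, 1.75 for Megf10, 1.68 for Rab44, 0.99 for Arpp21 and 1.04 for Abat, against 3.60, 3.22, 2.92, 2.79, 1.95 and 2.01 with it. The bounds for Myo18b and Abat hold only for background-corrected values, and of these 6 genes Abat lost its call without the correction (adjusted p = 0.0709, with 0.0134 to 0.569 over the alternatives). The highest adjusted p with 1 array left out was 0.0548 for Alox5, 0.0916 for Arpp21, 0.115 for Emilin2 and P2ry14 and 0.185 for Abat.

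Cdkn1a, which encodes the cell cycle inhibitor p21, was 6.96-fold higher in Scl-deleted cells. Its log2 fold change was 2.80 ± 0.46 (SE), from 6.20 ± 0.72 to 8.99 ± 0.86 (log2 intensity, SD, n = 3 each; limma adjusted p = 0.0339). The adjusted p rose to 0.115 without wild-type array 1, 0.116 without wild-type array 2, 0.0842 without Scl-deleted array 1 and 0.0796 without Scl-deleted array 2, while the log2 fold change lay between 2.33 and 3.16 with 1 array left out. It was 1.97 with the authors' normalized values (adjusted p = 0.0264) and 1.89 without background correction (adjusted p = 0.0384), and over all alternatives the adjusted p of Cdkn1a ran from 0.00827 to 0.474.

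Among the genes that fell, Serpina3b, a serine protease inhibitor gene, showed the lowest fold change, falling 5.39-fold from 7.73 ± 0.39 to 5.30 ± 0.37 (SD, n = 3 each; limma adjusted p = 0.00637), with signal above background on 2 of 3 Scl-deleted arrays. Selp, which encodes the alpha granule adhesion protein P-selectin, fell 3.16-fold from 9.15 ± 0.29 to 7.49 ± 0.17 (adjusted p = 0.00821). Pde10a, a cyclic nucleotide phosphodiesterase gene, fell 2.99-fold. Il6ra, the interleukin 6 receptor alpha chain, fell 2.80-fold, and Socs3, a feedback inhibitor of cytokine signalling, fell 2.78-fold. Tle1, a transcriptional co-repressor gene, Homer2 and Hebp1 fell 2.73-fold, 2.58-fold and 2.48-fold. Fam110c, Serpina3f and Fcgr2b, which encodes the inhibitory Fc gamma receptor, fell 2.46-fold, 2.46-fold and 2.44-fold. Serpina3b, Selp and Fcgr2b passed the threshold whichever array was left out, and for the others named here the highest adjusted p with 1 array left out ran from 0.0621 for Homer2 to 0.206 for Fam110c. Without background correction the log2 fold changes of Serpina3b, Fcgr2b, Serpina3f, Socs3, Tle1 and Fam110c were -1.28, -0.69, -0.71, -0.87, -0.91 and -0.78, against -2.43, -1.29, -1.30, -1.48, -1.45 and -1.30 with it. That of Il6ra was -0.96 with the mean of its probes against -1.48. Socs3 lost its call without the correction (adjusted p = 0.0612, with 0.00930 to 0.423 over the alternatives).

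**Figure D2:**
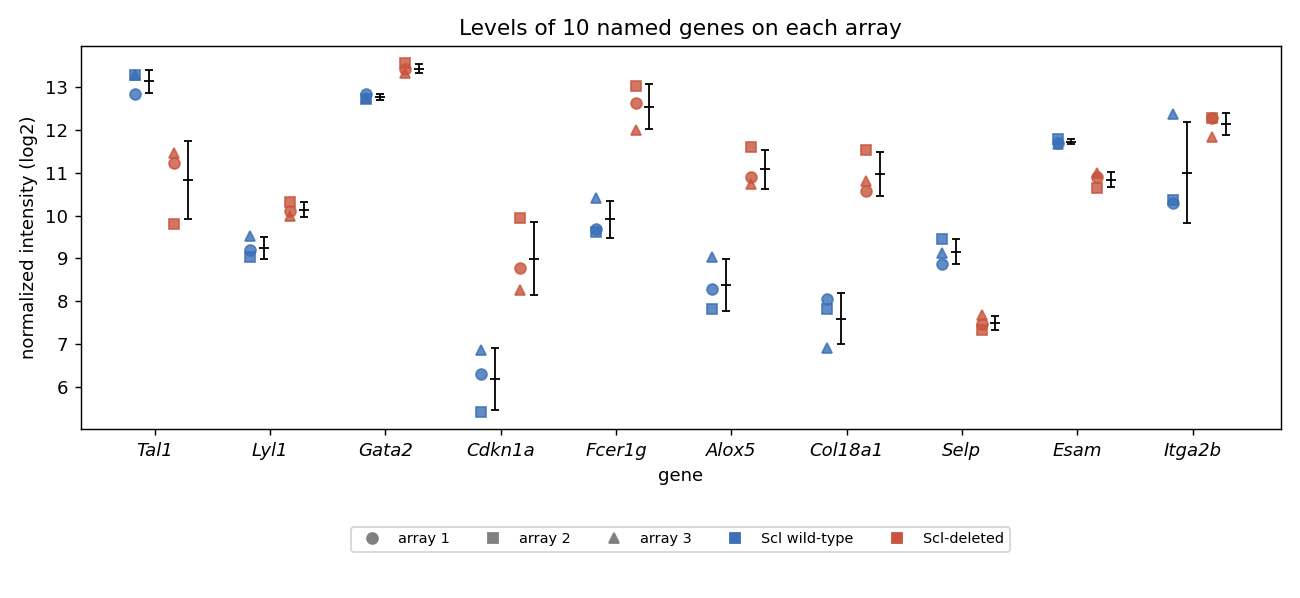
Normalized log2 intensities of 10 genes on each array, with wild-type arrays in blue, Scl-deleted arrays in red, marker shape giving the array number, and black bars giving the mean and SD of 3 arrays. Tal1, Selp and Esam were lower on all 3 Scl-deleted arrays, whereas the Itga2b groups overlapped, with wild-type arrays 1 and 2 at 10.29 and 10.36 and wild-type array 3 at 12.37.

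Of 23 tested genes in the list of SCL partners and megakaryocyte transcription factors, Tal1 fell, Lyl1 and Gata2 rose and 20 did not pass. The number called was also 3 when p was adjusted over the list alone. Lyl1, the closest relative of Tal1, rose 1.86-fold from 9.24 ± 0.25 to 10.14 ± 0.17 (SD, n = 3 each; limma adjusted p = 0.0453). Gata2, a zinc finger transcription factor gene of early progenitors and megakaryocytes, rose 1.58-fold from 12.77 ± 0.06 to 13.43 ± 0.11 (adjusted p = 0.0455). Both lost the call when any 1 array other than wild-type array 3 was left out, with adjusted p up to 0.209 and 0.236, and with median scaling (adjusted p = 0.0643 and 0.139). Over the alternatives the adjusted p ran from 0.00845 to 0.763 for Lyl1 and from 0.00484 to 0.569 for Gata2. The log2 fold changes of the SCL partners Lmo2 and Ldb1 were -0.09 and -0.06. Those of Gata1, Gfi1b, Nfe2 and Runx1 were 0.27, 0.16, -0.04 and -0.20, those of Fli1 and Mef2c were -0.39 and -0.52, and Klf1, an erythroid factor gene, had 0.22. None of these 9 genes passed. The dimmer kept probes of Mef2c were at -0.55 and -0.07, and that of Fli1 at -0.30. With 1 array left out, Gata1 ranged from 0.07 without Scl-deleted array 2 to 0.49 without wild-type array 3. Runx1 ranged from -0.38 without Scl-deleted array 1 to -0.08 without Scl-deleted array 3, and Klf1 from 0.09 without Scl-deleted array 2 to 0.39 without Scl-deleted array 1. Lmo2 changed sign without Scl-deleted array 2 and Nfe2 without wild-type array 1. Gfi1b and Ldb1 were at 0.08 and -0.03 without Scl-deleted array 1. The list as a whole had a median log2 fold change of -0.09 and did not pass (camera adjusted p = 0.286).

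The list of alpha granule and secreted platelet proteins was lower as a whole. Of its 21 tested genes, 15 had a lower mean in Scl-deleted cells, and only Selp passed on its own, against 5 genes when adjusted over the list alone. The median log2 fold change was -0.15 (camera adjusted p = 0.00706 with a preset correlation), and the call was lost with an estimated correlation (adjusted p = 0.536) and without Scl-deleted array 3 (adjusted p = 0.0914, median -0.05), while without Scl-deleted array 2 the median was -0.25. It was -0.10 with the authors' normalized values, -0.09 without background correction and -0.08 without the detection filter, and the median deviation from each gene's mean was -0.28 on Scl-deleted array 3 against -0.06 and 0.00 on Scl-deleted arrays 1 and 2. In alternatives chosen after the data were seen it was -0.31 with the Xist level as a covariate, -0.40 on the 4 Xist-positive arrays and -0.08 against wild-type array 3 alone. Over the alternatives the adjusted p ran from 1.66e-04 to 0.536. Pdgfb, F5, Clu and Angpt1 had log2 fold changes of -0.90, -1.12, -0.95 and -1.27 but did not pass (adjusted p = 0.0562, 0.0998, 0.140 and 0.231). Pdgfb passed with the authors' normalized values (adjusted p = 0.0326), without background correction (adjusted p = 0.0384) and with the trend and robust prior (adjusted p = 0.0230). It also passed with the mean of a gene's probes (adjusted p = 0.0480) and without wild-type array 3 (adjusted p = 0.0412), and its range was 0.0212 to 0.548. Angpt1 was at -1.86 without wild-type array 3 (adjusted p = 0.00862), with 0.998 the highest of its alternatives. Vwf, which encodes von Willebrand factor, had -0.43 and among the alternatives passed only with the trend and robust prior (adjusted p = 0.0298, with 0.843 the highest), and Pf4, which encodes platelet factor 4 and whose promoter drives Cre here, had -0.07, between -0.18 without wild-type array 3 and 0.04 without wild-type array 1.

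Platelet receptors and adhesion genes did not move one way. Of 25 tested genes Fcer1g rose, Esam, which encodes an endothelial and platelet adhesion molecule, fell 1.84-fold (adjusted p = 0.0277), and 23 did not pass; 5 passed when adjusted over the list alone, and the camera adjusted p was 0.648. Itga2b, the integrin alpha IIb gene, had a log2 fold change of 1.13 ± 0.49 (SE, limma adjusted p = 0.310), and without wild-type array 3 it was 1.81 (adjusted p = 0.00603), while over the alternatives the adjusted p reached 0.998. Slamf1 and Tbxa2r had -1.92 and 0.48 and did not pass (adjusted p = 0.0977 and 0.121). Slamf1 passed without Scl-deleted array 3 (log2 fold change -2.52, adjusted p = 0.00620) and with median scaling (adjusted p = 0.0396), and Tbxa2r with the authors' normalized values (adjusted p = 0.0494) and without background correction (adjusted p = 0.0492). Over the alternatives the adjusted p ran from 0.00620 to 0.854 for Slamf1 and from 0.0281 to 0.981 for Tbxa2r. Of the 29 tested genes for the demarcation membrane, tubulin and platelet release, 21 were higher and none passed, also 0 when adjusted over the list alone (median 0.14, camera adjusted p = 0.245). Of 33 platelet signalling genes, 15 were higher and none passed, against 1 when adjusted over the list alone (median -0.10, camera adjusted p = 0.309), with Lat at 0.70 and Rasgrp2 at 1.30. Without wild-type array 3, Lat at 0.75 and Rasgrp2 at 1.76 passed (adjusted p = 0.0300 and 0.00626). Lat also passed with the authors' normalized values (adjusted p = 0.0337) and without background correction (adjusted p = 0.0350), while over the alternatives the adjusted p of Lat and Rasgrp2 reached 0.693 and 0.998. Esam lost its call without wild-type array 1 or 2 or Scl-deleted array 1 or 2, with adjusted p up to 0.136.

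The list of haematopoietic stem and early progenitor genes was lower, with 18 of 22 tested genes below wild-type and a median log2 fold change of -0.37 (camera adjusted p = 3.68e-04). The call was lost with an estimated correlation (adjusted p = 0.536), and over the alternatives the adjusted p ran from 2.96e-05 to 0.536. The median deviation from each gene's mean was -0.26 and -0.29 on Scl-deleted arrays 1 and 2 but 0.02 on Scl-deleted array 3, and between 0.17 and 0.26 on the wild-type arrays. The list median was -0.17 without the detection filter, and in alternatives chosen after the data were seen it was -0.22 with the Xist level as a covariate, -0.18 on the 4 Xist-positive arrays and -0.23 against wild-type array 3 alone. Esam fell, while Pdzk1ip1, a membrane protein gene that lies next to Tal1 among the tested genes, rose 2.14-fold (limma adjusted p = 0.0284), and 8 genes passed when adjusted over the list alone. Pdzk1ip1 lost its call without wild-type array 2 or Scl-deleted array 1 or 2, with adjusted p up to 0.131. Tek, Slamf1 and Cd34, which encode surface proteins of stem and early progenitor cells, had log2 fold changes of -0.64, -1.92 and -0.89, and Satb1 had 0.94; these 4 did not pass. Satb1 was at 1.09 without wild-type array 3 (adjusted p = 0.0215) and Slamf1 at -2.52 without Scl-deleted array 3 (adjusted p = 0.00620), while over the alternatives the adjusted p reached 0.860 and 0.854. Kit, the stem cell factor receptor gene, had 0.19, between 0.07 without wild-type array 2 and 0.32 without wild-type array 3. A dimmer kept probe of Kit, above background on 4 arrays, was at -0.18.

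Neutrophil and promyelocyte markers were lower, with 14 of 16 tested genes below wild-type, none called alone, 0 when adjusted over the list alone, and a median of -0.44 (camera adjusted p = 8.53e-04; with an estimated correlation, adjusted p = 0.536). Without wild-type array 3 the median was -0.22 (adjusted p = 0.0137), and the median deviation from each gene's mean was -0.12 on wild-type array 1, 0.25 and 0.31 on wild-type arrays 2 and 3, and between -0.38 and -0.12 on the Scl-deleted arrays. Prtn3, Lyz2 and S100a8 had log2 fold changes of -0.68, -0.42 and -0.87, and Lyz2 -0.28 without Scl-deleted array 3. This list lost its call under the stricter detection filter (adjusted p = 0.0699), and over the alternatives its adjusted p ran from 2.61e-07 to 0.536. Ribosome biogenesis and Myc target genes were lower in 27 of 33 cases, with a median of -0.17 and none called alone, also 0 when adjusted over the list alone (camera adjusted p = 0.00706; with an estimated correlation, adjusted p = 0.536). Of its members with the smallest p, Ddx18, Nolc1 and Gnl3 had log2 fold changes of -0.38, -0.39 and -0.37 and Polr1c 0.53. Gnl3 was at -0.20 without Scl-deleted array 2 and Polr1c at 0.21 without wild-type array 2. Its call was lost without wild-type array 3 (adjusted p = 0.117), without Scl-deleted array 3 (adjusted p = 0.0525) and with median scaling (adjusted p = 0.0616), and over the alternatives it ran from 0.00105 to 0.536. Without Scl-deleted array 2 the median was -0.0934 (adjusted p = 0.0233).

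Histone genes were higher, with 33 of 37 tested genes above wild-type and a median of 0.30 (camera adjusted p = 3.61e-04), but none passed alone and 0 passed when adjusted over the list alone. The estimated correlation among these near-identical genes was 0.483, and with it the adjusted p was 0.634. H4c6, H4c8 and H4c3 had log2 fold changes of 0.51, 0.52 and 0.62. Without wild-type array 3, H4c6 and H4c8 passed at 0.61 and 0.63 (limma adjusted p = 0.0378 and 0.0447, up to 0.998 over the alternatives). Probes of histone genes may bind transcripts of several copies, so these are not separate measurements. The median deviation from each gene's mean was -0.25 and -0.39 on wild-type arrays 1 and 2, 0.09 on wild-type array 3, and between -0.01 and 0.41 on the Scl-deleted arrays. The list median was 0.17 without wild-type array 2, 0.45 without wild-type array 3 and, in alternatives chosen after the data were seen, 0.50 on the 4 Xist-positive arrays and 0.19 with wild-type arrays 1 and 2 averaged. Against wild-type array 3 alone, a comparison chosen after the data were seen, the median was 0.02 (adjusted p = 0.852, with 1.53e-07 the lowest of the alternatives).

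**Figure D3:**
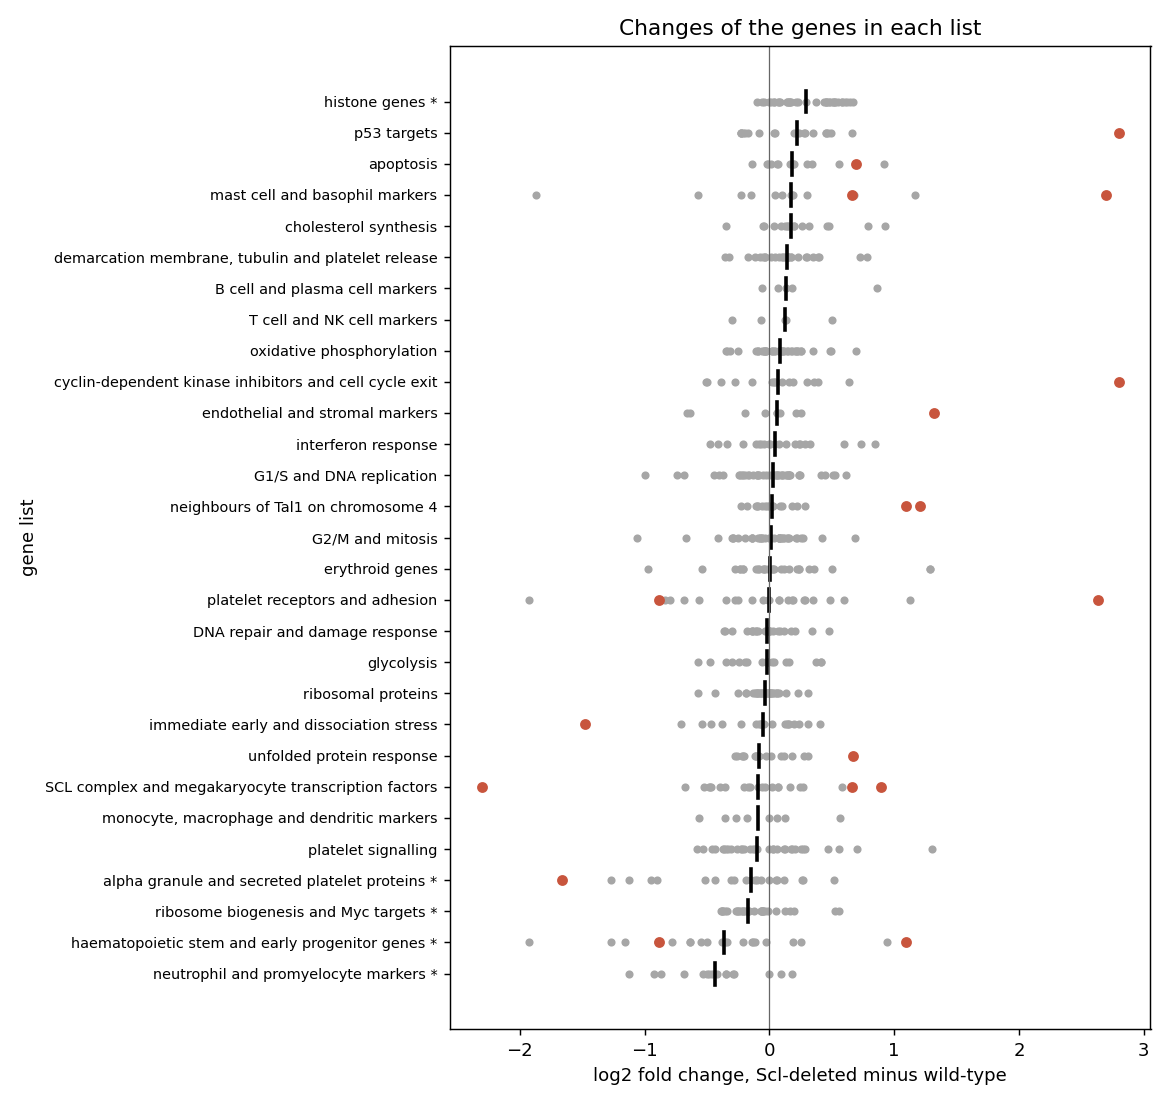
Log2 fold change of Scl-deleted over wild-type cells for the genes of 29 lists, with 1 point per tested gene, red where the adjusted p was under 0.05, and a black bar at the median. Asterisks mark the 5 lists with a camera adjusted p under 0.05 at the preset correlation, from neutrophil and promyelocyte markers at -0.44 to histone genes at 0.30.

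Lists tied to the cell cycle and cell death did not pass with all 6 arrays and the detection filter. Of 16 genes for cyclin-dependent kinase inhibitors and cell cycle exit, Cdkn1a alone was called, also 1 gene when adjusted over the list alone (median 0.07, camera adjusted p = 0.741). G1/S and DNA replication genes had a median of 0.03 over 45 genes (adjusted p = 0.706), and G2/M and mitosis genes 0.01 over 38 (adjusted p = 0.590), with no gene called in either and 0 in each when adjusted over the list alone. Ccnd1, the cyclin D1 gene, had a log2 fold change of 0.61 (limma adjusted p = 0.145), and 0.72 without wild-type array 3 (adjusted p = 0.0473, up to 0.998 over the alternatives). The dimmer kept probes of Ccnd1 were at 0.38, 0.51, 0.94 and 1.19. On the last of these wild-type array 3 was at 8.64, against 7.25 and 7.61 on wild-type arrays 1 and 2. The Scl-deleted arrays were between 8.80 and 9.13 on it. For p53 targets the median was 0.22 over 21 genes, with Cdkn1a the only call, also when adjusted over the list alone (camera adjusted p = 0.241), and Xpc and Zmat3 were at 0.45. The p53 list passed without the filter on dim probes (adjusted p = 0.0342, with 0.112 the next lowest and 0.716 the highest of the alternatives). DNA repair genes had a median of -0.02 over 23 genes (adjusted p = 0.566) and 0 calls when adjusted over the list alone. In the apoptosis list, Bcl2, which encodes a survival protein, rose 1.62-fold (limma adjusted p = 0.0399), and the median over 14 genes was 0.18 (camera adjusted p = 0.115), with 1 gene passing when adjusted over the list alone; the list passed without Scl-deleted array 1 (adjusted p = 0.0420, with 0.634 the highest of the alternatives). Bcl2 kept its call only without wild-type array 3 among the fits with 1 array left out, with adjusted p up to 0.209 in the others, and lost it with median scaling (adjusted p = 0.0857) and with the mean of its probes (log2 fold change 0.52, adjusted p = 0.115), with a range of 0.00845 to 0.769 over all alternatives.

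Markers of other blood cells were tested because a sort can hold other cells. Mast cell and basophil markers had a median of 0.18 over 14 genes (camera adjusted p = 0.426), with Alox5 and Gata2 called and 5 genes passing when adjusted over the list alone. Prss34 and Cpa3, which encode mast cell and basophil proteases, went opposite ways at -1.87 and 1.17, and neither passed; without Scl-deleted array 1 Cpa3 was at 1.54 (adjusted p = 0.0469, up to 0.866 over the alternatives). Erythroid genes had a median of 0.00 over 28 genes (adjusted p = 0.741), with Hbb-bt at 1.29, Hba-a1 at 1.28 and Car2 at -0.97, none called and 1 when adjusted over the list alone. Without Scl-deleted array 2, Hbb-bt and Hba-a1 were at 0.69 and 0.66. Car2 passed with the authors' normalized values (adjusted p = 0.0416), with the trend and robust prior (adjusted p = 0.0263) and without wild-type array 3 (log2 fold change -1.18, adjusted p = 0.0115), with 0.899 the highest of its alternatives. Monocyte, macrophage and dendritic markers had a median of -0.09 over 8 genes (adjusted p = 0.437), B cell and plasma cell markers 0.13 over 5 (adjusted p = 0.309), and T cell and NK cell markers 0.12 over 5 (adjusted p = 0.927), with 1, 1 and 0 genes passing when adjusted over the list alone. In the endothelial and stromal list, with a median of 0.06 over 10 genes (adjusted p = 0.807), Sp7, an osteoblast transcription factor gene, rose 2.49-fold (limma adjusted p = 0.0463), with 2 genes passing when adjusted over the list alone. The log2 fold change of Sp7 was 1.32, against 0.77 with the authors' normalized values (adjusted p = 0.0584) and 0.74 without background correction (adjusted p = 0.0739). Its adjusted p was up to 0.209 with 1 array left out and ran from 0.0121 to 0.708 over all alternatives. Eosinophil markers were not tested as a list because 2 genes were kept, with a median of -1.09 and neither called, against 1 when adjusted over the list alone; without wild-type array 3 the median was -0.58.

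Among metabolic and stress lists, none passed with all 6 arrays and no covariate. The medians were 0.08 over 39 genes for oxidative phosphorylation, -0.02 over 18 for glycolysis and 0.17 over 16 for cholesterol synthesis, with camera adjusted p of 0.333, 0.309 and 0.144 and 0, 2 and 0 genes passing when adjusted over the list alone. Interferon response genes had 0.04 over 21 (adjusted p = 0.566) and ribosomal proteins -0.03 over 36 (adjusted p = 0.286), both with 0 calls when adjusted over the list alone. In the unfolded protein response list, with a median of -0.08 over 17 genes (adjusted p = 0.792), Hspa5, the endoplasmic reticulum chaperone gene, rose 1.59-fold (limma adjusted p = 0.0374), the 1 call also when adjusted over the list alone. The Hspa5 probe was dim, at log2 intensities of 5.85 ± 0.05 in wild-type and 6.52 ± 0.07 in Scl-deleted cells (SD, n = 3 each). The lowest detected signal was 5.27 to 5.40 by array. Its log2 fold change of 0.67 became 0.35 with the authors' normalized values and 0.31 without background correction. The call of Hspa5 was lost with both (adjusted p up to 0.115), with median scaling (adjusted p = 0.189), with the trend and robust prior (adjusted p = 0.0691) and without any 1 array other than wild-type array 3 (adjusted p up to 0.165). Over all alternatives the adjusted p of Hspa5 ran from 0.0108 to 0.510. In the immediate early and dissociation stress list, with a median of -0.05 over 20 genes (camera adjusted p = 0.241), Socs3 fell, and Fos and Dusp1 had -0.71 and -0.54 without passing (limma adjusted p = 0.0872 and 0.0947); 3 genes passed when adjusted over the list alone. Fos and Dusp1 passed with the authors' normalized values (adjusted p = 0.0408 and 0.0325), without background correction (adjusted p = 0.0487 and 0.0331) and with the trend and robust prior (adjusted p = 0.0213 and 0.0137), and Fos also without wild-type array 3 (adjusted p = 0.0378). Socs3 lost its call without background correction (adjusted p = 0.0612), and over the alternatives the highest adjusted p was 0.875 for Fos, 0.763 for Dusp1 and 0.423 for Socs3. This list passed without wild-type array 2 (adjusted p = 0.0377, median -0.08), and in 2 alternatives chosen after the data were seen: with the Xist level as a covariate (adjusted p = 0.0362, median -0.04) and against wild-type array 3 alone (adjusted p = 0.00281, median -0.31). The highest over the alternatives was 0.634. The camera direction was down while the median lay above 0 for the erythroid, G1/S, G2/M and endothelial lists, whose means were 0.06, -0.02, -0.03 and 0.05, and the mean of the unfolded protein response list was above 0, at 0.0031, beside its negative median.

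Genes that flank Tal1 on chromosome 4 were tested as a list because a floxed locus can carry linked variants. Of 19 tested neighbours, Pdzk1ip1 and Slc5a9 rose, the latter at least 1.72-fold because it was not well above background on any wild-type array, and the list median was 0.02 (camera adjusted p = 0.590); 2 genes passed when adjusted over the list alone. With 1 array left out, the adjusted p of Pdzk1ip1 and Slc5a9 rose to 0.131 and 0.123, and without background correction Slc5a9 was at 0.53 on the log2 scale, below its bound. Across the whole chromosome, 17 of 540 tested genes other than Tal1 were called, 3.15%, against 1.10% of genes elsewhere (Fisher's exact test, two-sided, adjusted p = 0.00539 over 20 chromosomes, chosen after the calls were seen). The unadjusted p was 2.70e-04, and over 4 alternatives it ran from 7.46e-05 without background correction to 0.0190 without the detection filter, where 5 of 1037 genes were called against 22 of 16617 elsewhere. Tle1 and Hyi, whose 2 kept probes went opposite ways, are among the 17 genes. Fisher's test treats genes as independent, although genes vary together, and it was not repeated with an array left out.

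The arrays differed in ways that the genotypes do not describe. Wild-type arrays 1 and 2 resembled each other more than any other pair, with 14 genes more than 2-fold apart, against 67 to 208 in the other pairs within a group. Wild-type array 3 was more than 2-fold apart from wild-type arrays 1 and 2 in 208 and 201 genes. From Scl-deleted arrays 1, 2 and 3 it was so in 158, 277 and 127. Identical deposited values numbered 199 between wild-type arrays 1 and 2. Wild-type array 3 shared 46 and 56 with them, and 164 to 182 with the Scl-deleted arrays. By these measures wild-type arrays 1 and 2 stood apart from the rest, a division that overlaps with genotype. The first principal component held 53.8% of the variance and placed wild-type arrays 1 and 2 at -22.5 and -24.3, wild-type array 3 at 1.04 and the Scl-deleted arrays between 8.13 and 27.4. With wild-type arrays 1 and 2 averaged as 1 sample, an alternative chosen after the data were seen, 16 genes passed, all among the 110. Xist, which is transcribed from the inactive X chromosome of female cells, lay at 10.53, 10.89 and 9.13 on the wild-type arrays and at 5.21, 5.80 and 10.52 on the Scl-deleted arrays, so Scl-deleted arrays 1 and 2 were close to background. Eif2s3y, a Y chromosome gene, was above background on all 6 arrays. It lay at 6.61, 7.06 and 7.91 on the wild-type arrays and at 8.49, 8.13 and 7.56 on the Scl-deleted arrays, so it was lowest on wild-type arrays 1 and 2. With the Xist level as a covariate, also chosen after the data were seen, 2 genes passed and all 110 kept their direction. Their log2 fold changes were a median of 0.891 times those without the covariate, from 0.652 to 1.15 times, and the SE a median of 1.34 times, with 3 residual degrees of freedom in place of 4. Tal1 was at -1.88 ± 0.49 (SE) against -2.30 ± 0.39, Cdkn1a at 2.08 ± 0.50 against 2.80 ± 0.46 and Col18a1 at 3.45 ± 0.46 against 3.37 ± 0.33.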

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

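The alternatives on Xist, on averaging wild-type arrays 1 and 2 and on wild-type array 3 alone were chosen after seeing the data. All 110 called genes kept their direction in every alternative that measured them. With 110 genes called (81 higher, 29 lower), the count stayed within 1.5 times with the authors' normalized values (124), no background correction, median scaling (86) and the mean of a gene's probes. Without a filter 27 passed (19 higher, 8 lower), with more genes tested, and Tal1 and Cdkn1a had adjusted p of 0.133 and 0.130 at log2 fold changes of -2.30 and 2.80. With the strict filter 69 passed (47 higher), and Cdkn1a was not kept. With trend and robust estimation 49 were lower, and Tal1, at -2.30, had an adjusted p of 0.0675. Array weights called 913 (574 higher, 339 lower), among them 51 named genes that had not passed, and an adjusted p under 0.10 called 204 (140 higher, 64 lower). The cause was not tested for the array weights or the prior. Over all alternatives the adjusted p ran from 0.0109 to 0.385 for Tal1 and from 0.00827 to 0.474 for Cdkn1a. Leaving out 1 array gave 16 to 695 genes (11 to 471 higher, 5 to 224 lower), 3 to 6 lists, -2.62 to -1.79 for Tal1 and 2.33 to 3.16 for Cdkn1a. The numbers of the arrays are not said to pair them. Deviations of same-numbered arrays from their group means correlated at 0.11, -0.27 and -0.18, which shows no pairing but, with 3 arrays per group, cannot exclude one. With the replicate block 50 genes passed (35 higher, 15 lower), and Cdkn1a, at 2.80, had an adjusted p of 0.0739. With Xist as a covariate 2 genes passed (2 higher, 0 lower), with Tal1 at -1.88 and Cdkn1a at 2.08. With the 4 Xist-positive arrays, 3 against 1, 1 gene passed (1 higher, 0 lower), with -1.66 and 2.07. With wild-type arrays 1 and 2 averaged 16 passed (11 higher, 5 lower), with -2.34 and 2.63. Against wild-type array 3 alone 0 passed in limma (0 higher, 0 lower; 487 at an unadjusted p under 0.05), with -2.46 and 2.14. In the fits with 1 array in a group, that array is assumed to vary like the others, and fewer arrays remain. With an estimated inter-gene correlation or with fry 0 lists passed, against 5. No chip was named, so the chip as a block was not run. Dim probes limit the rest: 8 called genes were not above background on any wild-type array and 1 on any Scl-deleted array.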

Other observations

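The tests on sex composition, the Fcer1g group and chromosome 4, and the count of other splits, were chosen after the results were seen; that on the other muscle genes was written before its result. The called genes below that are outside the report were chosen after their values were seen. Beside Alox5, Ltc4s, which encodes leukotriene C4 synthase, and Cysltr1, a cysteinyl leukotriene receptor gene, were higher, Ltc4s by 0.92 on the log2 scale and Cysltr1 at least 2.18-fold from a wild-type level not well above background. Other called genes that were higher include Cd72 at 1.70, Clec4d at 1.53, Lat2 at 1.45, Tnfrsf18 at 1.45, Il18r1 at 1.02 and Cxcr4 at 0.90. The receptor genes Fcgr2b and Il6ra were lower, at -1.29 and -1.48, as were Gnaz, which encodes the platelet G protein alpha z subunit, at -1.25, Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, at -1.11, and Hoxb5 at -0.93. Cd72, Clec4d, Fcgr2b and Gnaz passed whichever array was left out, and for the others of this paragraph, Alox5 included, the highest adjusted p with 1 array left out ran from 0.0548 to 0.216. No enrichment was tested.

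Of the 10 splits of the 6 arrays into 3 and 3, 1 split, the real one, gave as many as 110 called genes and the highest of the others gave 1 gene. At an unadjusted limma p under 0.05 the real split gave 1431 genes. Other splits that kept wild-type arrays 1 and 2 together, with Scl-deleted array 1, 2 or 3, gave 1352, 380 and 1104. Splits that separated these 2 arrays gave 103 to 227. Small p-values thus went with wild-type arrays 1 and 2 being grouped together as well as with genotype. The 10 splits are too few for a share under 0.05. Sex composition was tested on 75 genes, the 76 called without Scl-deleted array 3 less Xist itself; that array's Xist level was like that of wild-type arrays. On that array the median share of their change was 0.715, and 74 of 75 went the same way. A single array cannot decide whether sex is the cause. Eif2s3y was above background on all 6 arrays, so Xist alone does not give the sex composition of a sample. Its level was lowest on wild-type arrays 1 and 2, at 6.61 and 7.06, so sex composition may also differ between these arrays and the rest. With Xist as a covariate 2 genes passed and all 110 kept their direction, with log2 fold changes a median of 0.891 times and SE a median of 1.34 times those without it: the calls ended through smaller folds, larger SE, as Xist and genotype correlate at -0.648, and 3 residual degrees of freedom in place of 4. Only Scl-deleted array 3 sets the Xist level apart from genotype, so sex and genotype cannot be told apart reliably here. The closeness of wild-type arrays 1 and 2 overlaps with genotype as well. The effect of genotype, which the design names, stays open too.

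Fcer1g, Alox5, Ltc4s and Lat2, which are expressed in mast cells and other myeloid cells, rose with a median log2 change of 2.04. Other cells in the sort may bring such transcripts, and would bring their other abundant ones as well. The 13 other tested mast cell and basophil markers had a median of 0.17 (SD 0.73), the 16 neutrophil and promyelocyte markers -0.44 (SD 0.35) and the 8 monocyte, macrophage and dendritic markers -0.0918 (SD 0.35), each below 2.04 by more than its spread. Among the brightest of these markers, Gata2, Kit and Srgn, which megakaryocyte cells also express, were at 0.66, 0.19 and -0.15. Mpo and Lyz2 were at -0.29 and -0.42, and Cst3 at -0.01. The dimmer mast cell protease genes Cpa3, Cma1 and Tpsb2, chosen after their values were seen, were at 1.17, 0.18 and 0.10. Prss34, another protease gene of mast cells and basophils, went the other way, at -1.87. Fcer1g, Alox5, Ltc4s and Lat2 were chosen after their rise was seen, so a lower median of other markers was likely whatever the cause. Of the neutrophil markers 14 of 16 were lower, where admixture would raise them. For the markers tested, these values argue against admixture of neutrophils or promyelocytes. Of the monocyte, macrophage and dendritic markers 5 of 8 were lower, with a median closer to 0 than their SD. So few markers, with so small a shift, leave admixture of these cells undecided. For mast cells and basophils the values do not decide. There 9 of 13 other markers were higher, Cpa3 went the way mast cells would need and Prss34 the opposite way. The brightest of these markers are shared with megakaryocyte cells. A change within the sorted cells stays open, and the sort gate was not given in the sources used here.

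Called genes were concentrated on chromosome 4, which carries Tal1, in both directions: 11 higher and 6 lower besides Tal1, 17 of 540 genes against 92 of 8389 elsewhere. Fisher's exact test over 20 chromosomes gave an adjusted p of 0.00539 for chromosome 4 (odds ratio 2.93), and no other chromosome passed. Its unadjusted p went from 2.70e-04 to 0.0190 without the detection filter, with 5 of 1037 against 22 of 16617 genes. The test treats genes as independent, although genes vary together and all calls come from the same 6 arrays, so its p may be too small. It was not repeated with an array left out. Of the 17 genes, only Cd72 and Tpm2 passed whichever array was left out. A candidate explanation of the concentration is a segment of one parental strain linked to the floxed allele, whose variants could alter expression or probe binding. Among the 200 tested genes nearest to Tal1, 8 were called, against 9 of the other 340, an odds ratio of 1.53 with a 95% interval from 0.505 to 4.55, so the position along the chromosome does not decide. The 2 probes of Hyi went opposite ways, at -0.95 and 1.02, and strain genotypes were not analysed here.

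Myo18b, Tnni1, Tnni3, Tpm2 and Cryab, which are known from striated muscle, were all called higher. The hypothesis that muscle contractile genes may rise in general was tested on the 14 other tested genes of a list of 76. Their median log2 change was 0.20, 10 of 14 were higher (exact sign test, two-sided p = 0.180) and none was called, which leaves the hypothesis undecided.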
